A study of Mus musculus with 2 samples.

How the data were processed

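Single-cell RNA sequencing was done on liver metastases of 4T1 cells, a mouse triple-negative breast cancer line, grown in BALB/c mice. The injected cells carried either a scrambled control hairpin (shSCR) or a hairpin against Zdhhc17 (shZdhhc17), which encodes a palmitoyltransferase, an enzyme that attaches palmitate to proteins. Per the labels' protocols, 250000 cells were injected into the spleen, metastases were dissected under a microscope on day 14, and equal numbers of cells from 3 separate dissociations were pooled per group before loading on a BD Rhapsody cartridge (a microwell capture system) with a target of 15000 cells. Each group is therefore 1 library, and the cells of single mice cannot be told apart.

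Per the file headers, the authors ran the BD Rhapsody analysis pipeline, corrected the counts for ambient RNA (free RNA in the suspension), clustered the cells at high resolution, reclustered selected sets, and named cell classes and types from marker expression. Gene symbols follow the GRCm38 (mm10) build, per the file headers. Seurat 4.1.0 is named in the submitters' processing notes. The version of the Rhapsody pipeline and the ambient correction tool are not given in the sources used here. The cell tables hold, as the authors deposited them, whole-number counts per cell (total UMIs, which are molecule counts, and detected genes), and the percent of UMIs from mitochondrial genes, both after ambient correction. They also hold UMAP coordinates (a score with no fixed unit in the deposited tables), which served only to find the annotated neighbours of some labels. The neutrophil marker table lists the top 20 genes of each of 9 clusters. Its values are the authors' log2 fold changes of a cluster against all other neutrophils, from Seurat's Wilcoxon method on depth-scaled log2 counts with a pseudocount of 1, per the file headers. It also gives the deposited fraction of the cells of a cluster with the gene above 0, printed here as a percent, and the authors' specificity and marker scores. The fraction outside the cluster was not used here. The gene tables hold flags per gene only. Expression values per gene and library were not analysed here, so levels of single genes, Zdhhc17 included, were not compared between the libraries.

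No deposited cell had fewer than 500 UMIs, and no cell exceeded a mitochondrial share of 15.0%. The 10922 cells of the neutrophil table were all annotated as neutrophils in the full table. The authors' labels gave 17 cell types, 21 doublet labels and 3 unknown labels. Doublets and unknown cells were kept in the denominators, and no further doublet caller was run.

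Shares were computed as cells of a type over all cells of the library, or cells of a neutrophil cluster over all neutrophils of the library. Each share has an exact (Clopper-Pearson) 95% binomial interval, and each ratio of shares (shZdhhc17 over shSCR) has a log-normal 95% counting interval. These cover counting error only. With 1 library per group there was no test between groups, and the spread between mice is unknown. A share is called higher or lower where the exact intervals of the libraries did not overlap. These can overlap although the interval of the ratio leaves out 1, as for fibroblasts (1.01 to 1.28), so an overlap does not show equal shares. A count of 0 would allow a share of up to 0.0131% in shSCR and 0.0139% in shZdhhc17, from 3 cells.

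Before the data were examined, 20 gene lists (206 genes), the groups, the alternatives and the rule for named genes were fixed. The lists covered granule and precursor genes, mature circulating neutrophils, tumour-associated neutrophils, interferon-stimulated genes, hypoxia and glycolysis, NADPH oxidase subunits, cytokines and chemokines, killing effectors, antigen presentation, suppressive myeloid genes, dissociation stress, and markers of macrophages and monocytes, T and NK cells, B and plasma cells, dendritic cells, hepatocytes, 4T1 epithelium, endothelium, fibroblasts and stellate cells, and erythroid cells. The rule named the 8 genes with the highest log2 fold change in each cluster and every list member in the marker table. Its condition on an adjusted p could not be applied, since the marker table gives none, so all 180 listed markers were used. The 8 highest genes of each cluster came to 72, and the lists added 16. Each list was tested against each cluster's 20 markers by a one-sided Fisher's exact test with the 21544 genes of the neutrophil gene table as background and Benjamini-Hochberg adjustment over 180 pairs of list and cluster. Genes are not replicates, and this background includes genes too low to become markers. Planned results on cell cycle phase were not computed, since no phase or score per cell was used here.

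Alternatives were other denominators, filters on UMIs and mitochondrial percent, removal of the top 5% of UMIs, and matching of the libraries within 10 classes of UMIs. Others were added after the data were seen. The main addition thinned the UMIs of each shSCR cell at random by 0.811, the median shZdhhc17 to shSCR ratio of median UMIs over the 10 types other than neutrophils with at least 200 cells per library, or by 0.575, the ratio in neutrophils, and then applied the same minimum of 500. The others were a minimum of 1000 UMIs with and without thinning, removal of doublets and unknown cells, cells other than cancer cells as denominator of the neutrophil share (planned for the cell types), merging of numbered cluster pairs, and the listed markers as background of the list tests. The code was tested on simulated data. Simulated neutrophil clusters changed 1.5 times, before shares were rescaled to their sum, were called in 100% of 1000 trials, and unchanged ones in 0.444% of 4500. Simulated cells were drawn at random with no spread between mice, so these rates cover counting error only. A list with 5 members planted among 20 markers, the others drawn at random from the background genes, was found in 100% of 50 trials. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Gene positions come from GENCODE annotation of GRCm38, the same assembly as the files' symbols but not necessarily the same annotation release.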

Results

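The 2 libraries held 44371 cells, 22860 from control (shSCR) metastases and 21511 from metastases of ZDHHC17-silenced (shZdhhc17) cells. The shSCR library had 214842365 UMIs with a median of 7105 per cell, and the shZdhhc17 library had 172527305 with a median of 6732. Cancer cells, neutrophils and non-Kupffer macrophages were the 3 most abundant of the 17 annotated types in both libraries. Zdhhc17 (ENSMUSG00000035798.14, protein-coding, GRCm38 chromosome 10, 110941780 to 111010140, minus strand) was listed among the detected genes of all cells and of neutrophils. It was not among the 1000 most variable genes of either set, and its level per library was not analysed here. All values below come from 1 pooled library per group, so differences are set against counting error only.

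The first comparison asked how silencing Zdhhc17 in the injected cells went with the cellular makeup of the metastases. Cancer cells made up 36.9% of the shZdhhc17 library (95% interval 36.2 to 37.5) and 27.2% of the shSCR library (26.6 to 27.7), a ratio of 1.36 (1.32 to 1.40). Neutrophils, short-lived phagocytes of the innate immune system, made up 20.1% (19.6 to 20.7) against 28.8% (28.3 to 29.4), a ratio of 0.698 (0.675 to 0.721). The 11 immune types together came to 51.7% against 62.5%.

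Other myeloid types did not move together. Monocytes were at 7.47% in shZdhhc17 and 9.72% in shSCR (ratio 0.768, 0.722 to 0.817), and cells annotated as MDSCs were at 2.10% and 3.10% (ratio 0.678, 0.604 to 0.762). Kupffer cells, the resident macrophages of the liver sinusoids, were at 3.49% against 2.36% (ratio 1.48, 1.32 to 1.65). Non-Kupffer macrophages had nearly equal shares, 13.6% and 13.7% (ratio 0.997, 0.952 to 1.04). Conventional dendritic cells were at 1.11% and 1.32%, with overlapping intervals.

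Among the less abundant types, endothelial cells were at 1.83% in shZdhhc17 and 1.19% in shSCR (ratio 1.54, 1.32 to 1.79), and B cells at 1.35% and 0.971% (ratio 1.39, 1.17 to 1.65). T cells were at 1.74% and 1.85%, fibroblasts at 2.53% and 2.23%, and NK cells at 0.172% and 0.197%, all with overlapping intervals. Among cells with UMIs at or above the lower quartile, however, the T cell ratio was 0.419 (0.326 to 0.538), lower with separate intervals. That limit of 1925 UMIs lies between the library medians of T cells, so depth decides in part which of them stay. With the same filter B cells had overlapping intervals (ratio 1.35, 0.767 to 2.36). Hepatocytes (0.116% and 0.127%) and cholangiocytes, the lining cells of bile ducts (0.0511% and 0.0612%), were rare in both. In all, 4 of the 17 types were higher in shZdhhc17, 3 were lower and 10 had overlapping intervals. The intervals allow for no differences between mice.

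**Figure D1:**
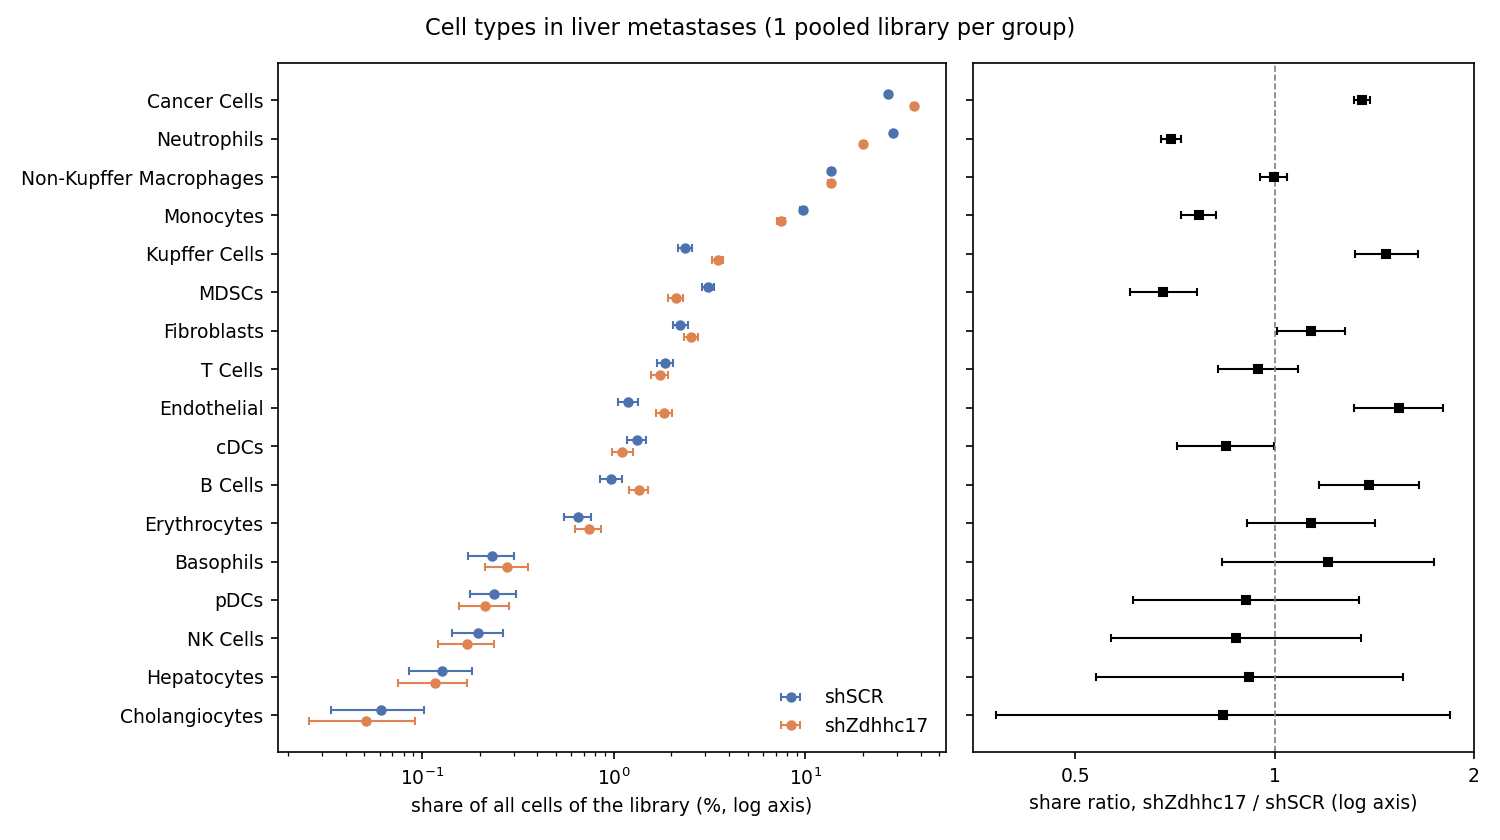
Share of each annotated cell type in the 2 libraries (left, percent of all cells on a log axis, bars are exact 95% binomial intervals) and the ratio of the shares (right, log axis, bars are 95% counting intervals). Neutrophils lie at a ratio of 0.698 and cancer cells at 1.36, while non-Kupffer macrophages lie at 0.997.

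Because shares sum to the whole, the types were also compared among cells other than cancer cells. Neutrophils then made up 31.9% of the shZdhhc17 library (31.1 to 32.7) and 39.6% of the shSCR library (38.9 to 40.3), a ratio of 0.805. Monocytes were at 11.8% and 13.3%, and MDSCs at 3.33% and 4.25%. Kupffer cells were at 5.52% and 3.24%, endothelial cells at 2.90% and 1.63%, and B cells at 2.13% and 1.33%. Non-Kupffer macrophages (21.6% and 18.8%) and fibroblasts (4.01% and 3.06%) were higher in shZdhhc17 with this denominator. Among cells with low mitochondrial percent, monocytes were not lower (ratio 1.06, 0.978 to 1.16) and erythrocytes were higher (2.14, 1.59 to 2.88). MDSCs and endothelial cells then had overlapping intervals (0.731 and 1.28). The limit of 5.57% lies between the library medians of monocytes (5.10% in shZdhhc17 and 5.67% in shSCR) and of erythrocytes (3.41% and 6.08%). The filter itself therefore decides in part which of these cells stay.

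The depth per cell was lower in the shZdhhc17 library in each of the 17 types. Cancer cells had a median of 10531 UMIs in shZdhhc17 and 13075 in shSCR, and non-Kupffer macrophages 6959.5 and 8362. The difference was wider in neutrophils, with medians of 1418 and 2464 UMIs (ratio 0.575, 0.531 to 0.62) and 772 and 1001.5 detected genes, and in T cells, with 1130 and 2051.5 UMIs (ratio 0.551). Over the 10 types other than neutrophils with at least 200 cells per library, T cells included, the ratios ranged from 0.551 to 0.889 with a median of 0.811. Neutrophils without a single mitochondrial UMI made up 31.3% of shZdhhc17 neutrophils and 15.3% of shSCR neutrophils, against 0.307% and 0.863% of non-Kupffer macrophages.

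**Figure D2:**
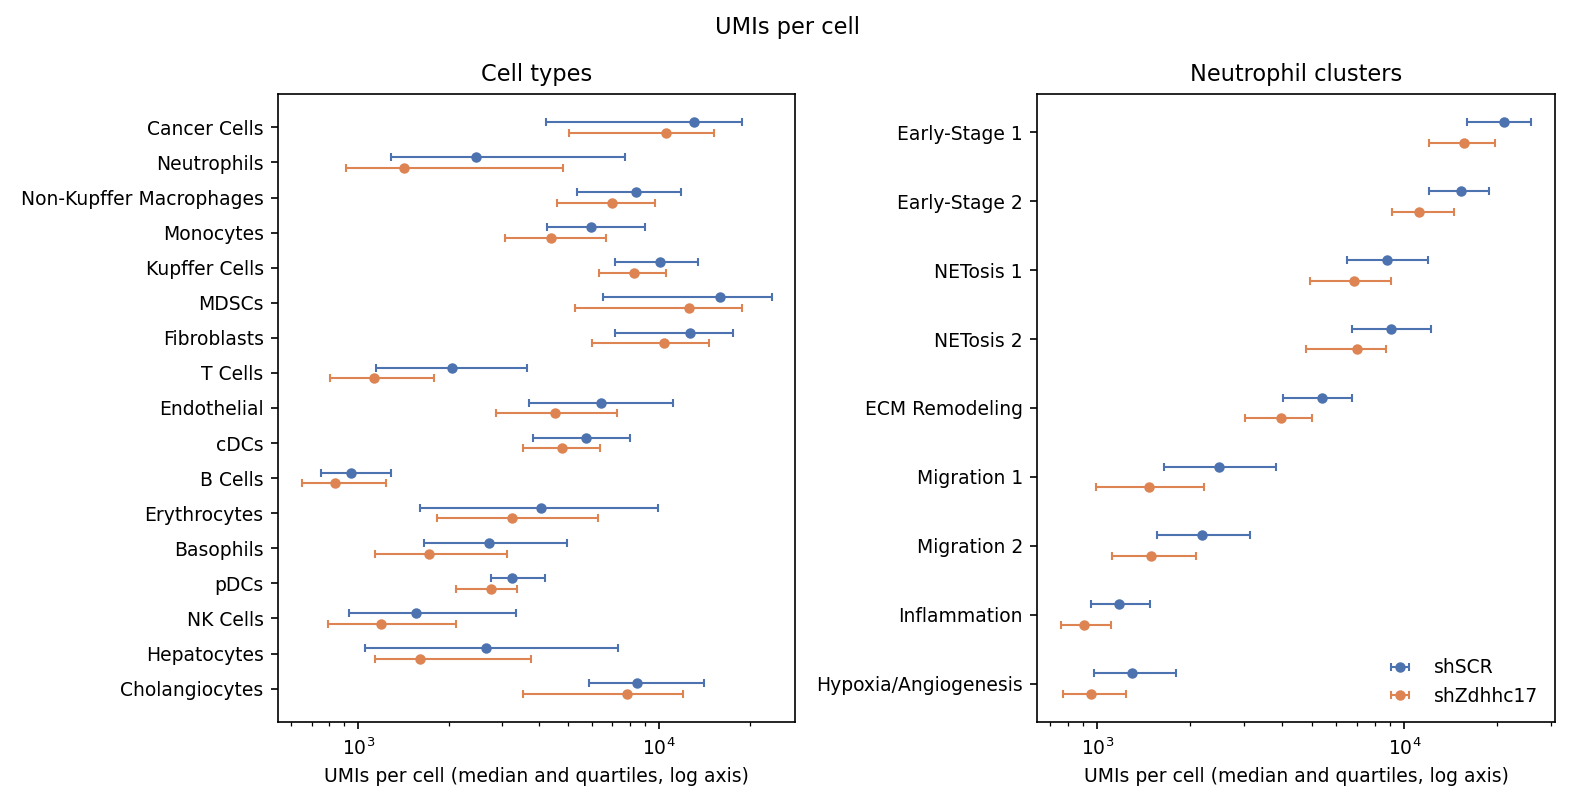
Median UMIs per cell (points, log axis) with the lower and upper quartiles (bars) for each cell type (left) and each neutrophil cluster (right) in the 2 libraries. Neutrophils had medians of 1418 UMIs in shZdhhc17 and 2464 in shSCR, and their clusters ranged from the Early-Stage clusters with the most UMIs to Inflammation and Hypoxia/Angiogenesis with the fewest.

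The second comparison concerned neutrophil states, for which the authors defined 9 clusters among 6594 shSCR and 4328 shZdhhc17 neutrophils. The following marker values are from the authors' deposited table and compare a cluster with all other neutrophils, not the libraries. The Early-Stage 1 cluster was led by the azurophil granule genes Mpo (log2 fold change 4.92), which encodes myeloperoxidase, and Ctsg (4.72), Elane (4.47) and Prtn3 (3.95), which encode serine proteases. Mpo was detected in 99.6% of its cells. Early-Stage 2 was led by Fcnb (2.33), and also held the proliferation genes Mki67 (1.97), Top2a (1.91) and Pcna (1.91). NETosis 1 had Ltf (3.00), Camp (2.58), Ngp (2.57) and Lcn2 (1.75), which encode proteins of the specific granules, and Cybb (2.15), the catalytic NADPH oxidase subunit. NETosis 2 had Chil3 (2.11), a chitinase-like protein gene, Cd177 (1.64), Hmgb2 (1.49) and the NADPH oxidase subunit gene Cyba (0.69).

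In the authors' deposited table, ECM Remodeling was led by Stfa3 (log2 fold change 3.45), Cstdc5 (2.73) and Stfa2 (2.64) of the stefin A family, with Ly6g (2.16) and Mmp9 (1.40), which encodes gelatinase B. The stefin genes are close copies of each other, so how reads were split among them is uncertain. Migration 1 was led by Retnlg (2.09), Wfdc17 (1.79) and the collagenase gene Mmp8, and Migration 2 by Stfa2l1 (1.54), Saa3 (1.54) and Mmp19 (1.39), with the chemokine receptor gene Cxcr2 (0.87). Inflammation was led by Il1b (2.05), which encodes a pyrogenic cytokine. It also held Ccrl2 (1.58), Cd84 (1.60), the chemokine receptor gene Cxcr4 (1.66) and the immediate-early genes Fos (1.28), Junb (1.39) and Zfp36 (1.29), which were on the list of dissociation stress genes. Hypoxia/Angiogenesis was led by Hilpda (3.67) and Basp1 (3.21), with Bnip3 (2.95), Egln3 (2.39), the chemokine genes Cxcl3 (3.09) and Cxcl2 (2.72), the glucose transporter gene Slc2a1 (2.00) and Cd274 (2.62), which encodes PD-L1.

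**Figure D3:**
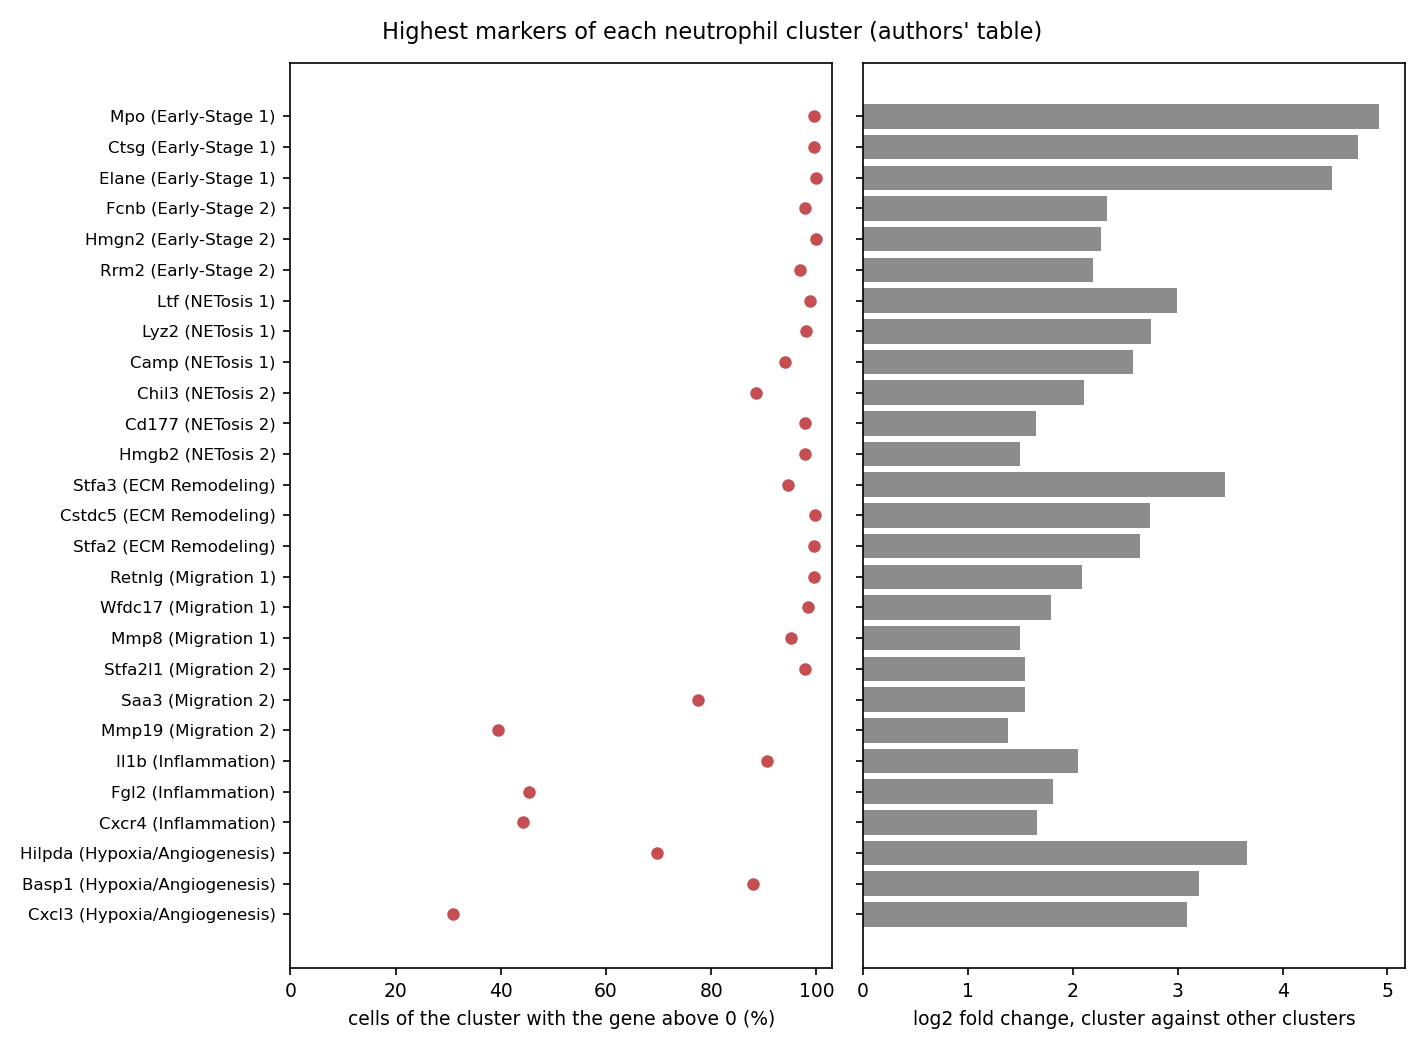
The 3 markers with the highest log2 fold change of each neutrophil cluster in the authors' deposited table, with the percent of the cells of that cluster in which the gene was above 0 (left) and the log2 fold change (right). Mpo was detected in 99.6% of Early-Stage 1 cells. Clusters differed in UMIs per cell (shSCR medians of 21152 in Early-Stage 1 and 1175 in Inflammation), so percents of different clusters are not comparable.

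The markers ranked first by the authors' marker score lie on GRCm38 at these protein-coding genes. Mpo is on chromosome 11 (87793581 to 87804413), Fcnb on chromosome 2 (28076378 to 28084885), Ltf on chromosome 9 (111019271 to 111042767) and Chil3 on chromosome 3 (106147554 to 106167564). Stfa3 (36450537 to 36455392), Stfa2l1 (36156811 to 36161953) and Retnlg (48872621 to 48874496) are on chromosome 16. Il1b is on chromosome 2 (129364570 to 129371139) and Basp1 on chromosome 15 (25363277 to 25413764).

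Of the fixed lists, the granule and precursor list had all 14 members among the markers, 4 each in Early-Stage 1, Early-Stage 2 and NETosis 1 (adjusted p = 2.42e-08 each, one-sided Fisher's exact test with Benjamini-Hochberg adjustment). The hypoxia and glycolysis list had 5 members, all in Hypoxia/Angiogenesis (Bnip3, Egln3, Ero1l, Hilpda and Slc2a1, adjusted p = 3.13e-10 by the exact test). The authors named this cluster from the same marker genes. The mature neutrophil list had 2 members each in ECM Remodeling, Migration 1 and Inflammation, and 3 of the dissociation stress genes were in Inflammation (exact test, adjusted p = 3.37e-06). Cytokine and chemokine genes were in Inflammation (Il1b and Ccrl2) and Hypoxia/Angiogenesis (Cxcl2, Cxcl3 and Il1rn), and 3 killing effectors, Ctsg, Elane and Mpo, were in Early-Stage 1. No antigen presentation gene and no macrophage, T, NK, B, dendritic, endothelial, fibroblast or erythroid marker was among the 180 listed markers. Only 7 of 13 macrophage and monocyte, 2 of 6 endothelial and 3 of 7 fibroblast genes were in the background. With 20 markers per cluster, the lack of these genes does not show that such cells are absent. The hepatocyte list had Trf in Migration 1 (adjusted p = 0.0119, exact test), the only member of that list in the background, but did not pass with all genes as background (adjusted p = 0.0551, exact test) or with markers of log2 fold change of 1 or more. The 4T1 epithelial list had Lcn2 in NETosis 1, which is also a granule gene. In all, 14 of 180 pairs of list and cluster passed by the exact test. With the 180 listed markers themselves as background, 1 pair passed, the hypoxia list in Hypoxia/Angiogenesis (adjusted p = 0.00187, exact test).

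The makeup of the neutrophils differed between the libraries in 6 of the 9 clusters. NETosis 1 made up 4.99% of shZdhhc17 neutrophils (4.36 to 5.68) and 11.6% of shSCR neutrophils (10.8 to 12.4), a ratio of 0.431 (0.373 to 0.499). Migration 1 was at 7.23% against 11.7% (ratio 0.616, 0.543 to 0.699), and Hypoxia/Angiogenesis at 15.6% against 21.0% (ratio 0.744, 0.684 to 0.808). Inflammation was at 28.6% (27.2 to 29.9) against 18.1% (17.2 to 19.0), a ratio of 1.58 (1.47 to 1.69). NETosis 2 was at 8.25% against 6.16% (ratio 1.34, 1.17 to 1.54), and Migration 2 at 13.9% against 10.7% (ratio 1.30, 1.17 to 1.44). Early-Stage 1 (7.37% and 7.16%), Early-Stage 2 (6.03% and 6.04%) and ECM Remodeling (8.04% and 7.55%) had overlapping intervals.

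**Figure D4:**
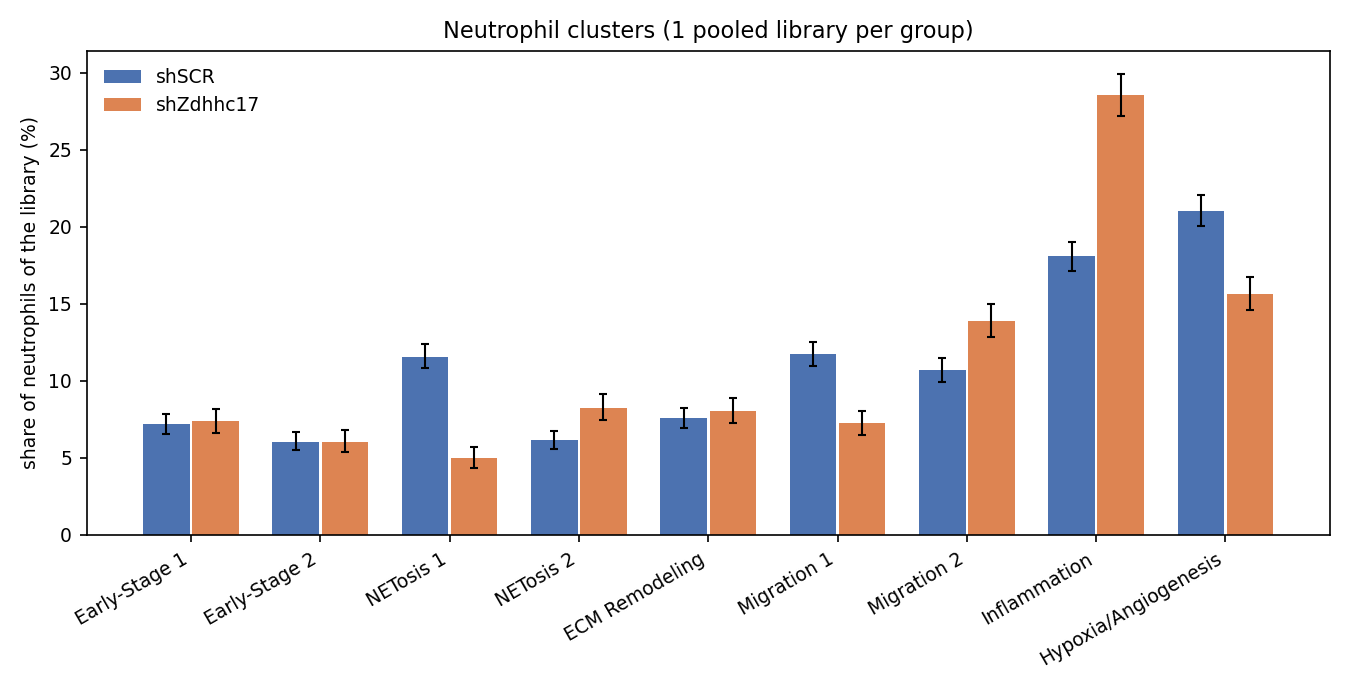
Share of each neutrophil cluster among the neutrophils of the 2 libraries (percent, bars start at 0, error bars are exact 95% binomial intervals). Inflammation made up 28.6% of shZdhhc17 and 18.1% of shSCR neutrophils, and NETosis 1 made up 4.99% and 11.6%.

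The Inflammation difference depended on how depth was handled. This cluster had medians of 906 UMIs in shZdhhc17 and 1175 in shSCR, and 58.0% and 37.7% of its cells had no mitochondrial UMI. After the libraries were matched on UMIs, its ratio was 1.08 (1.00 to 1.17), with overlapping intervals, and among neutrophils with UMIs at or above the lower quartile it was 0.924 (0.817 to 1.04). That limit of 1093 UMIs lies between the medians of this cluster in the 2 libraries, so the depth difference itself decides which of its cells stay. With the shSCR cells first thinned by 0.811, the ratio of the other types, and a minimum of 1000 UMIs in both, it was 1.46 (1.30 to 1.64), though neutrophils differed more in depth than that. The 5 other clusters that differed kept their direction and separate intervals under matching, with ratios of 0.560 for NETosis 1, 1.71 for NETosis 2, 0.678 for Migration 1, 1.51 for Migration 2 and 0.562 for Hypoxia/Angiogenesis. Among neutrophils with low mitochondrial percent, of which few belonged to the NETosis clusters, NETosis 1 (0.653, 0.385 to 1.11) and NETosis 2 (1.88, 1.04 to 3.41) had overlapping intervals. Early-Stage 1 (1.69), Early-Stage 2 (1.49) and ECM Remodeling (1.38) were higher in shZdhhc17 after matching. Matching raised the ratio of each of the 7 clusters with more UMIs per cell than Inflammation and Hypoxia/Angiogenesis. A higher matched ratio is therefore in part made by matching. It lowered the ratios of Inflammation and Hypoxia/Angiogenesis, so the 0.562 of Hypoxia/Angiogenesis is in part made by it too. Thinning the shSCR cells by the neutrophil ratio of 0.575 gave Hypoxia/Angiogenesis a ratio of 0.82 (0.752 to 0.894), though the depth ratio of this cluster itself was 0.737.

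The clusters of the NETosis and Migration pairs differed in opposite directions, while the Early-Stage clusters had overlapping intervals unless cells were filtered or matched on UMIs. Both Migration clusters together made up 21.1% of shZdhhc17 and 22.4% of shSCR neutrophils (ratio 0.942, 0.876 to 1.01), and both NETosis clusters 13.2% and 17.7% (ratio 0.747, 0.681 to 0.819). As shares of all cells rather than of neutrophils, no cluster was higher in shZdhhc17 with separate intervals. Inflammation then made up 5.75% and 5.21% of all cells (ratio 1.10, 1.02 to 1.19), NETosis 2 1.66% and 1.78%, and Migration 2 2.79% and 3.08%. The other 6 clusters were lower, from NETosis 1 at 1.00% and 3.34% (ratio 0.301) to ECM Remodeling at 1.62% and 2.18% (ratio 0.743).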

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

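The rule that picked the labels below was chosen after the shares were seen, and no other test was made of them. These labels belong to cells that the authors set apart as doublets, which were kept in the denominators but not compared as types. The label D15 held 0.102% of the shZdhhc17 library and 0.00437% of the shSCR library, 22 cells against 1. Its cells had a median of 5677 UMIs and 1077 genes, and a median of 4.22 for UMIs per gene within a cell, and their nearest annotated neighbours on the UMAP were B cells. The label D12 held 0.33% of the shZdhhc17 library and 0.105% of the shSCR library, 71 cells against 24, next to fibroblasts. The label D5 held 1.36% and 1.02%, 293 cells against 234, next to neutrophils. Each was picked out because its share in the shZdhhc17 library lay above that in the control library with separate exact intervals, among 24 doublet and unknown labels. The labels D2 (0.358% in shZdhhc17 and 0.599% in shSCR) and D4 (0.669% and 1.27%) were lower in shZdhhc17 with separate intervals, and the other 19 had overlapping intervals. All doublets together made up 5.73% and 5.69% of cells. No technical or biological explanation was tested for these labels.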

How the results depend on the processing

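Thinning, the minimum of 1000 UMIs, the non-cancer denominator of the neutrophil share (planned for the cell types), the removal of doublets and unknown cells, merged pairs and the marker background were chosen after the data were seen. The number of cell types with separate intervals (7 of 17) stayed between 5 and 8 under all 7 alternatives, though the called types changed as given below. The count is out of 11 types among immune cells and 16 without cancer cells. The neutrophil share ratio of 0.698 stayed below 1 with separate intervals in all 8, of which 1 takes the same cells from the neutrophil table. It was 0.844 among immune cells, 0.805 among cells other than cancer cells, 0.515 with UMIs at or above the lower quartile, 0.582 with at least 1000 UMIs, and 0.622 when that minimum followed thinning of the shSCR cells. The ratio of monocytes went from 0.768 to 1.06 at low mitochondrial percent, and that of the Inflammation cluster from 1.58 to 0.924 at UMIs at or above the lower quartile. The cause was not tested. The limits on UMIs lie between the library medians of neutrophils, T cells, basophils, hepatocytes, Inflammation cells and Hypoxia/Angiogenesis cells, so depth decides in part which of these stay. Hypoxia/Angiogenesis went from 0.744 to 0.552 at UMIs at or above the lower quartile. The limit of 5.57% on mitochondrial percent likewise lies between the library medians of monocytes, B cells and erythrocytes. For neutrophil clusters the limit of 1.33% lies between the library medians of all neutrophils. Mitochondrial percent thus decides in part which of these cells stay. Low mitochondrial percent also ended the calls of MDSCs (0.731), endothelial cells (1.28), NETosis 1 (0.653) and NETosis 2 (1.88), and made erythrocytes (2.14) and ECM Remodeling (1.63) higher. The UMI quartile ended the call of B cells (1.35) and made T cells lower (0.419) and both Early-Stage clusters (1.35 and 1.30) and ECM Remodeling (1.39) higher. Among immune cells monocytes (0.929, 0.876 to 0.986) lost their call, though this ratio interval stayed below 1, and non-Kupffer macrophages (1.21) were higher. The number of neutrophil clusters with separate intervals (6 of 9) went to 3 of 6 when numbered pairs were merged, as the NETosis pair became 1 call and the opposite shifts of the Migration pair cancelled (0.942, overlapping intervals), and stayed between 5 and 8 otherwise. The ratio of UMIs per cell was 0.948 for medians and 0.853 for means. The list tests gave 14 pairs, 13 with all genes as background, 15 with markers of log2 fold change of 1 or more (both without the hepatocyte pair), and 1 with the listed markers as background, which holds fewer genes. Of 168 other values, 113 moved by less than their counting interval and 53 by more without a change of a called direction. At low mitochondrial percent both Early-Stage clusters gave no ratio, since at least 1 library had no such cells left. The planned cell cycle alternative was not run. No paired analysis was possible because each group has 1 pooled library, and for the same reason no replicate could be left out. The number of cells limits the rare types, such as the 25 cholangiocytes.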

Other observations

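Chosen after the values were seen were the tests of variable genes and of the spread in cancer cells, the test of dilution (its denominator was planned for the cell types), the library count behind each group difference, and the matching tests within the NETosis and Migration pairs and of Inflammation, which were split off once matching of all 6 clusters had left the question open. The genes that the authors flagged as most variable among neutrophils were compared with the fixed lists. Of 22 interferon-stimulated genes, 17 were variable, among them Isg15, Ifit1, Rsad2 and Cxcl10 (adjusted p = 7.99e-18, one-sided Fisher's exact test over 20 lists). Ifitm1 and Ifitm3 were listed markers, of which there are only 20 per cluster. The background of the test includes genes too low to be variable. Other lists passed it too, such as the erythroid genes (adjusted p = 4.94e-05, Fisher's exact test). Of the 14 tumour-associated neutrophil genes present, 13 were variable, including Siglecf, Ccl3, Ccl4, Vegfa and Ptgs2, and 4 were listed markers (Cxcr4 and Nfkbia in Inflammation, Cd274 and Hilpda in Hypoxia/Angiogenesis). Of the cytokine and chemokine genes, 13 of 14 were variable, including Tnf, Il1a and Osm, and 5 were listed markers. Of the dissociation stress genes, 10 of 11 were variable. Among genes of other lineages, 4 of 5 erythroid genes were variable (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt), against 0 of 7 macrophage and monocyte, 0 of 10 T and NK, 0 of 6 dendritic and 0 of 3 fibroblast markers present. Values were 10 of 14 for granule, 10 of 16 for hypoxia, 6 of 10 for killing, 7 of 15 for suppressive, 3 of 12 each for mature and antigen presentation genes, 1 of 6 each for NADPH oxidase and 4T1 epithelial, 1 of 8 for B cell, 1 of 2 for endothelial and 1 of 1 for hepatocyte genes.

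Of 37 fine clusters that held the 14135 cancer cells, 15 were higher in shZdhhc17, 11 were lower and 11 had overlapping intervals. The most uneven had 87 shSCR cells and 1 shZdhhc17 cell, a ratio of 0.00900 (0.00125 to 0.0646), another had 107 and 494 cells (ratio 3.61), and 7 of the 37, 4 of them uneven, held 2539 cells with medians under 2000 UMIs against 11513 in all cancer cells. All 26 uneven clusters kept separate intervals after the libraries were matched on UMIs, so the shares were uneven among cells of like UMIs too. Matching moved many of them further in the direction they already had, such as cluster 1 (3.15 to 4.04) and cluster 6 (0.441 to 0.349). Others moved back, such as cluster 32 (2.92 to 2.66). It was thus a weak check, and whether lower depth moved cells between clusters was not tested. The spread of log2 ratios beyond counting noise, without the most uneven cluster, was 1.16 against 0.723 in neutrophils, 0.607 in monocytes and 0.532 in non-Kupffer macrophages, and its ratio of 1.60 to the largest (1.10 to 2.14 over resampled clusters) leaves a library effect common to all types open, as the lower bound was under the 1.5 set to exclude it. A difference between the injected lines, such as the hairpin or the clones that grew out, may be the cause and stays open too, since each group has 1 library.

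The lower neutrophil share could come from shallow cells lost under the UMI minimum, from dilution by cancer cells, or from a difference between the metastases. Thinning the shSCR cells by 0.811, the depth ratio of the other types, removed 118 cells, 19 of them neutrophils. It left the ratio at 0.696 (0.673 to 0.72), which argues against the minimum as the cause at that depth difference. Neutrophils differed more in depth. Thinning by their own ratio of 0.575 left 6113 of 6594 shSCR neutrophils and a ratio of 0.700 (0.676 to 0.724), but it thinned all types alike. Cells not called before deposit were not tested. Among cells other than cancer cells the ratio was 0.805 (0.78 to 0.83), so dilution can account for part of the difference and not the whole. A difference between groups or between the pooled mice stays open with 1 library per group.

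The neutrophil clusters moved apart between the libraries, the NETosis and Migration clusters within each pair. Of the 6 clusters with separate intervals, 5 kept them in the same direction after matching on UMIs. All 6 were required to exclude depth as the cause, so the test of the whole set is undecided. Matching also moved NETosis 2, Migration 2 and Hypoxia/Angiogenesis further in the direction they already had, so it was a weak check of them. Matched on UMIs among the cells of a pair alone, the ratio of the share of its first cluster was 0.575 (0.509 to 0.650) for NETosis and 0.688 (0.609 to 0.777) for Migration. Before matching it was 0.578 and 0.654. The clusters of a pair had like medians, such as 8747 and 9036.5 UMIs for NETosis in shSCR, so matching could hardly move it. Unequal UMIs within a pair thus did not account for these 2 splits, but whether lower depth moved cells between its clusters was not tested. For Inflammation the matched ratio was 1.08, while thinning the shSCR cells by the neutrophil ratio of 0.575 gave 1.76. That factor lies below the depth ratio of every cluster (0.593 to 0.785, Inflammation 0.771), so it thinned these cells by more than they differed. Hypoxia/Angiogenesis, of like depth (medians of 954 and 1295 UMIs against 906 and 1175), was lower instead (0.744). Cells were not reassigned to clusters at lower depth, so depth cannot be told apart from a change of state. The spread of fine-cluster ratios in neutrophils was 1.19 times that in monocytes, which leaves open a library effect on clustering, and the group difference stays open with 1 library each.

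As values only, the lower depth of neutrophils was tested against the other types and against the cluster mix, and is not weighed further. The neutrophil ratio of median UMIs, 0.575, lay within the 0.551 to 0.889 of the 10 other types, though 9 of these were above it. With the shSCR cluster mix in both libraries it was 0.664 (0.622 to 0.710), still below their median of 0.811. The libraries held 1.52 and 1.43 times the 15000 cells targeted per cartridge. The doublet labels D2 and D11 had medians of 785.5 and 693.5 UMIs, below the neutrophil medians.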
